A study of Mus musculus with 10 samples.

How the data were processed

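RNA sequencing of whole colon was compared between mice lacking Vista and wild-type (WT) mice, all given 2% dextran sulfate sodium (DSS) in drinking water for 7 days. DSS damages the colonic epithelium and causes colitis. Vista is an immune checkpoint protein encoded by the gene Vsir. The labels described 10 libraries, 5 per genotype. A first deposited table held 3 libraries of each genotype and a second deposited table held 2 of each. The labels of the first 6 libraries called the genotype a knockdown, those of the other 4 and the design text called it a deletion, and the design text stated 3 replicates per group. All 5 libraries were treated as 1 Vista knockout group. The design text called its replicates biological, but the labels did not tie the 4 later libraries to animals, so p-values measure the spread between these libraries. A chi-square comparison of counts over all pairs of libraries, within and between genotypes, found no pair that differed by only counting noise, with a mean chi-square per row of 4.56 for the closest pair, WT 2 and WT 3. Within a genotype the farthest pair was knockout 4 and knockout 5, at 27.7.

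The values were read counts per Ensembl gene identifier, not normalised, as deposited by the authors. Per the submitters' processing notes, reads of the first 6 libraries were aligned with HISAT2 2.2.1 and counted with featureCounts 2.0.1, with the build named as GRCh38, a human assembly. For the other 4 libraries the notes named HISAT2, featureCounts 2.0.1 and the mouse build mm10. The annotation and any strand setting were not given in the sources used here. Both tables held the same 55416 rows in the same order. Gene names came from the identifiers through GENCODE M21, an mm10 annotation, which named 52083 of the identifiers and left 3333 without a name. Of the unnamed, 2147 carried identifiers beginning ENSMUSG00002, none of which M21 held. Rows with no name stayed in the tests and library totals, where they held 0.358% to 0.410% of a library's counts. Library totals ran from 3691322 to 4071238 counts.

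Whether a row's counts followed its gene name was checked without reference to genotype, on 1196 genes of families that practically every cell uses, such as ribosomal, proteasome and translation genes. A gene passed with 500 counts or more over all libraries. A region was a run of 10 or more passing genes in chromosome order, trimmed by 1 gene at each end, except that a run beginning with the first such gene of a chromosome was extended to position 1, as on chromosomes 4 and 6. The rule gave 3 regions in mm10, namely chromosome 4 from 1 to 59904737, chromosome 6 from 1 to 30304539 and chromosome 15 from 10446756 to 38078854, with 1416 rows, 527 of them protein-coding. Gene names are used for results only inside them.

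The region rule was written after the tables were seen. A hidden Markov segmentation had been tried first with minimums of 100 and 1000 counts and other transition probabilities, before the run rule was chosen. Members of the families with tissue-restricted expression had been left out after they were seen to interrupt runs. Genotype calls inside nearly identical regions set by hand had also been seen before the rule was final. That all 46 universally used genes inside the regions passed therefore follows from how the regions were built and is no evidence for them. In 1000 shuffles of the genes, after the same exclusions, 8 gave a run as long as the minimum, and the longest held 10 genes. The runs held 25 genes on chromosome 4, 15 on chromosome 15 and 10 on chromosome 6, so the chromosome 6 region was no longer than shuffles reached. The choice was examined with 24 region rules, crossing the exclusions, minimums of 100, 500 and 1000, runs of 7 and 10, and trimming.

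Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, its expression filter, the quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. The pooled comparison carried the deposited table as a covariate. Each table was also fitted alone, and the interaction of genotype and table was tested. For 47 gene lists, camera from limma 3.58.1 was run with a preset correlation of 0.01 and with an estimated one, together with fry. CPM values, counts scaled to a common library total, were computed from the deposited counts. On simulated data of 9736 rows, with known changes of 1.5-fold in 67, 2-fold in 67 and 4-fold in 66 of them, the pooled fit recovered 43.3% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, with 6 false calls among 159. The first-table fit recovered 34.3%, 83.6% and 100%, and the second-table fit 9.0%, 19.4% and 89.4%, at the same folds. Changes were planted only in rows of at least 5 CPM. The simulated libraries had no shift between tables and no libraries standing apart, so these rates are for simpler data than the real ones.

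Tests, gene lists, most alternatives and the naming rule were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, no filter or a stricter one of 5 CPM, a fold minimum, no table covariate, a surrogate variable from sva 3.50.0, omission of immune receptor, mitochondrial and sex-linked rows, and omission of each library in turn. The naming rule took the 12 largest increases and 12 largest decreases that passed the threshold with a mean of at least 1 CPM and the same sign in both tables, after leaving out 135 unnamed or clone rows, plus members of the lists with the smallest p. None of the 24 rows it picked by fold lay inside the regions, so these 24 are not named as genes. The rule was applied again inside the regions after the data were seen, which is a departure from the fixed rule. It named 7 increases and 12 decreases there. The list part of the rule added Car9, Pax5, Ddx58, Sdc2, Spink4, Col1a2, Tpm2, Cox6c and Ndufa4, and repeated genes already named by fold, among them Tac1 and Pdk4. A result of this comparison is not reported here. Another 12 genes were chosen after their values were seen, namely Tmem246, Acnat1, Pon2, Ccdc107, Gba2, Galnt12, Rida, Cftr, Slc35a1, Tox, Galt and Hint2. Row names outside the regions are given only where they describe the tables.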

Results

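Colon RNA was sequenced from 5 Vista knockout and 5 WT mouse libraries after 7 days of 2% DSS. The libraries came in 2 deposited count tables, the first with 3 of each genotype and the second with 2 of each. Total counts ran from 3691322 in WT library 5 to 4071238 in knockout library 2, and between 17185 and 18965 rows held a count in a library.

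Genes that every cell uses were nearly empty in most of the genome. Actb, the gene of cytoplasmic beta-actin, had 75 counts over all 10 libraries, the elongation factor gene Eef2 had 1, and the epithelial genes Krt8, Krt18 and Epcam had 0, 0 and 2. All 37 mitochondrial rows together had 0 counts. The rows with the most counts were Eif4b with 701947, Axl with 496907, Trim56 with 319780 and the olfactory receptor row Olfr332 with 316215. Of 1150 universally used genes outside the regions defined above, 335 (29.1%) reached 500 counts, and their median was 30 counts. Inside the 3 regions the median of such genes was 15983, but the regions were built from genes that reached 500 counts, which raises it. Colon epithelial genes were also counted inside, with 130813 counts for the intestinal cadherin gene Cdh17 and 99645 for the transcription factor gene Klf4. The regions held 9.96% to 10.7% of a library's counts. Outside them, a row name was not taken to identify the transcript counted.

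**Figure D1:**
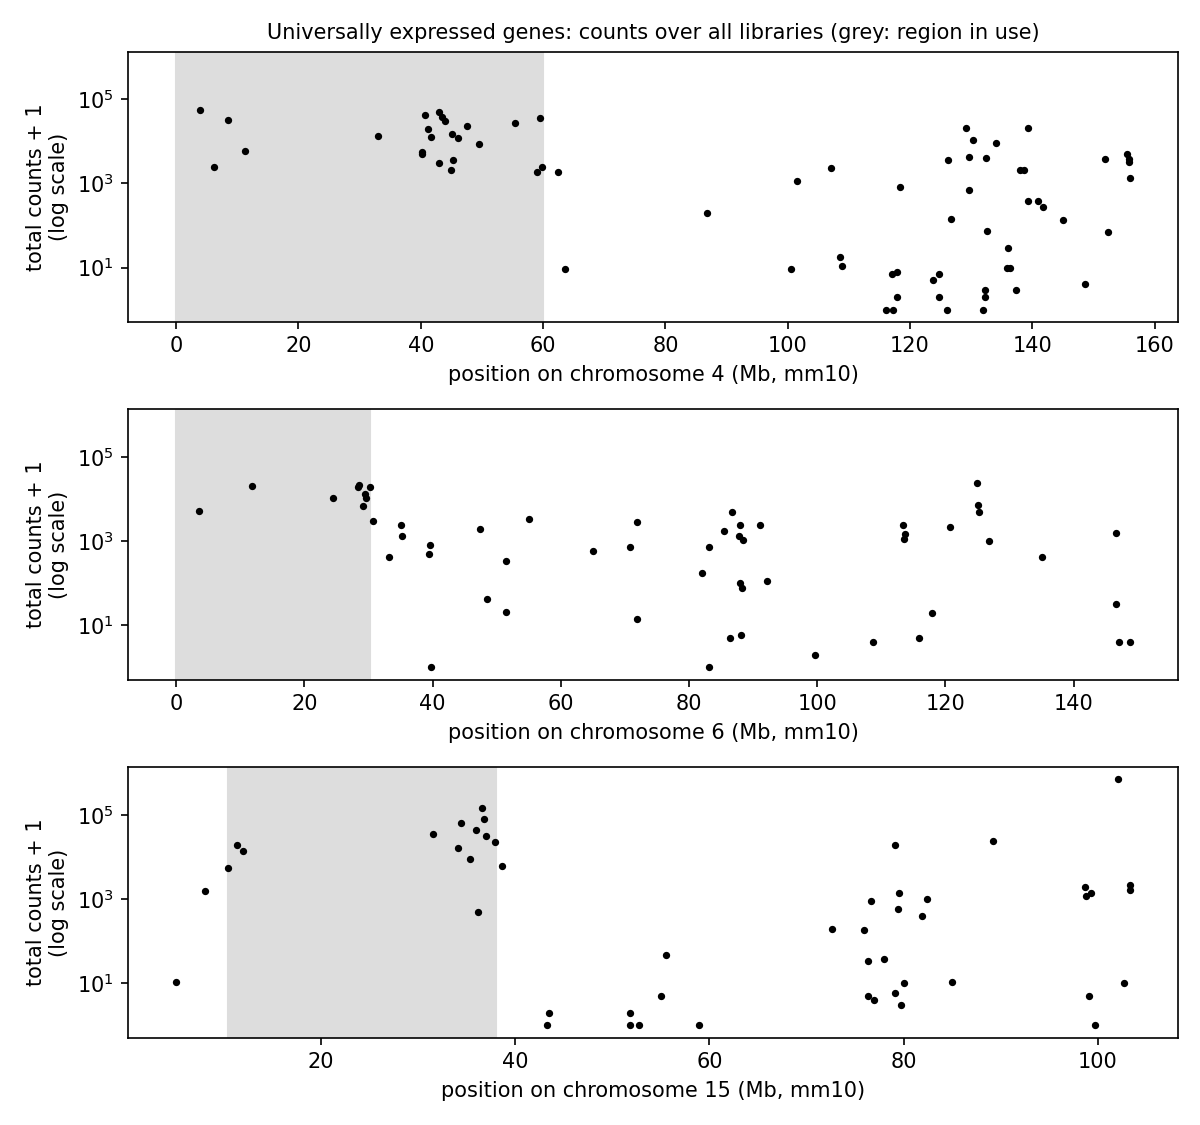
Total counts over the 10 libraries, plus 1 and on a log scale, of universally used genes against their mm10 position in Mb on chromosomes 4, 6 and 15. Each point is 1 gene and grey marks the regions whose gene names are used. Tissue-restricted family members are left out here as in the region rule. All 46 genes inside the regions have 500 counts or more, because the regions were built that way.

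The targeted gene, Vsir, is at chromosome 10 from 60346851 to 60372684 on the plus strand, outside the regions, and overlaps Cdh23 on the minus strand. Its row (ENSMUSG00000020101) held 27, 49, 33, 97 and 40 counts in knockout libraries 1 to 5 and 42, 78, 82, 5 and 0 in WT libraries 1 to 5. The log2 fold change of knockout over WT was 0.55 ± 0.77 (SE), with an adjusted p of 0.702 by edgeR. The sign turned to −0.02 without WT library 5 and to −0.74 with voom. Since the row lies where names did not follow transcripts, it does not check the genotype labels, and they remain unchecked here.

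The main comparison asked which colon transcripts differ between Vista knockout and WT mice in DSS colitis. Folds are those of the edgeR fit with the table as a covariate, and can differ from the ratio of the means given beside them. Inside the regions, Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, was 3.80-fold lower in knockout colons, at 9.40 ± 2.75 CPM against 37.5 ± 18.5 in WT (SD, n = 5 each). Penk, the precursor gene of enkephalin peptides, was 2.03-fold lower, at 78.9 ± 26.9 against 162 ± 33.4 CPM. Tac1, the precursor gene of substance P, was 2.82-fold higher, at 401 ± 241 against 124 ± 40.0 CPM. B4galt1, a galactosyltransferase gene, was 1.65-fold higher, at 1013 ± 260 against 621 ± 140 CPM.

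Of 429 rows tested inside the regions, 38 differed by edgeR's quasi-likelihood test, 8 higher and 30 lower in the knockout. Of these, 32 carried a gene name and 6 were unnamed or clone models. For each of the 32, all 5 knockout libraries lay on the same side of the WT mean of their table. The 32 were selected by a test on these same libraries, which favours such agreement, so it is no separate support. Single libraries of the genotypes could still overlap. In Slc35a1, which fell, knockout 1 had 585.8 CPM and WT 1 had 575.2. The log2 fold change of Pdk4 (ENSMUSG00000019577, chromosome 6 from 5483351 to 5496309) was −1.93 ± 0.28 (SE) with an adjusted p of 0.00526. It was −1.76 in the first table alone and −2.16 in the second. Tac1 (ENSMUSG00000061762, chromosome 6 from 7554879 to 7565834) had 1.498 ± 0.25 with an adjusted p of 0.00826, and 1.98 and 0.72 in the separate tables. The adjusted p of Tac1 in edgeR was 0.0525 without the table covariate and 0.350 in the second table alone. For its interaction of genotype and table the adjusted p was 0.0796. The names Pdk4, Tac1, Met, Tmem229a, Tfpi2, Gng11, Ahcyl2, Pon2 and Cftr rest on the chromosome 6 region, whose run of 10 genes was no longer than the longest in shuffles and which 14 of 24 region rules gave. Penk lost the call without knockout library 1 and without WT library 1, 2 or 4, with adjusted p values of 0.0671 to 0.0775 in edgeR. B4galt1 lost it without WT library 4 (0.0504) and without the table covariate (0.0674).

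Other genes that rose were Nr4a3, a nuclear receptor gene (log2 1.12), Dnaic1, a gene of the ciliary dynein (0.93), Tmem64 (0.73), Enho, the gene of the peptide adropin (0.68), and Met, the hepatocyte growth factor receptor gene (0.42). Dnaic1 and Enho overlap at their ends on opposite strands. Adjusted p values of these 5 ran from 0.00826 for Tmem64 to 0.0416 for Met in edgeR. Nr4a3, Enho and Met each lost the call in 9 of 18 alternatives, and Tmem64 without the table covariate.

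Among genes that fell, Tmem229a had a log2 fold change of −1.69, the ciliary gene Anks6 −1.39 and Tfpi2, a serine protease inhibitor gene, −1.36. Adamts12, a secreted metalloprotease gene, had −1.14 and Gng11, a G protein subunit gene, −1.03. On chromosome 15, where 20 of the 24 region rules gave a region, lie Adamts12, Ank, Cmbl and Rida. Ank, a pyrophosphate transporter gene whose row overlaps Otulin, had −0.97, Zfp462 −0.81, Cmbl −0.78 and Ahcyl2 −0.78. Car9, a carbonic anhydrase gene induced by hypoxia, fell by 0.57 on the log2 scale with an adjusted p of 0.00790 in edgeR. Further falls, in genes chosen after their values were seen, were −0.69 for Cftr, the epithelial chloride channel gene, −0.60 for Pon2, −0.75 for Tmem246 and −0.76 for Acnat1, whose reads the counting could have split with the related neighbouring gene Acnat2. Galnt12 had −0.59, Slc35a1 −0.39, Gba2, which overlaps Rgp1 and Creb3, −0.46, and Galt −0.32. Rida had −0.49, Tox −0.59, Hint2 −0.39 and Ccdc107, which overlaps Rmrp, −0.62. The row of Galt overlaps other genes. Anks6, Tfpi2, Zfp462, Cftr, Galnt12, Slc35a1, Gba2, Galt, Rida, Tox and Hint2 each lost the call without WT library 4, with adjusted p values of 0.0597 to 0.127 in edgeR. All of these lost it without at least 1 other library too. Of 18 alternatives, Galt lost the call in 13, Hint2 in 12, Zfp462 in 10, and Slc35a1 and Tox in 9 each. Anks6, Rida and Cftr lost it in 6 each, Tfpi2 and Gba2 in 5 each and Galnt12 in 2.

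**Figure D2:**
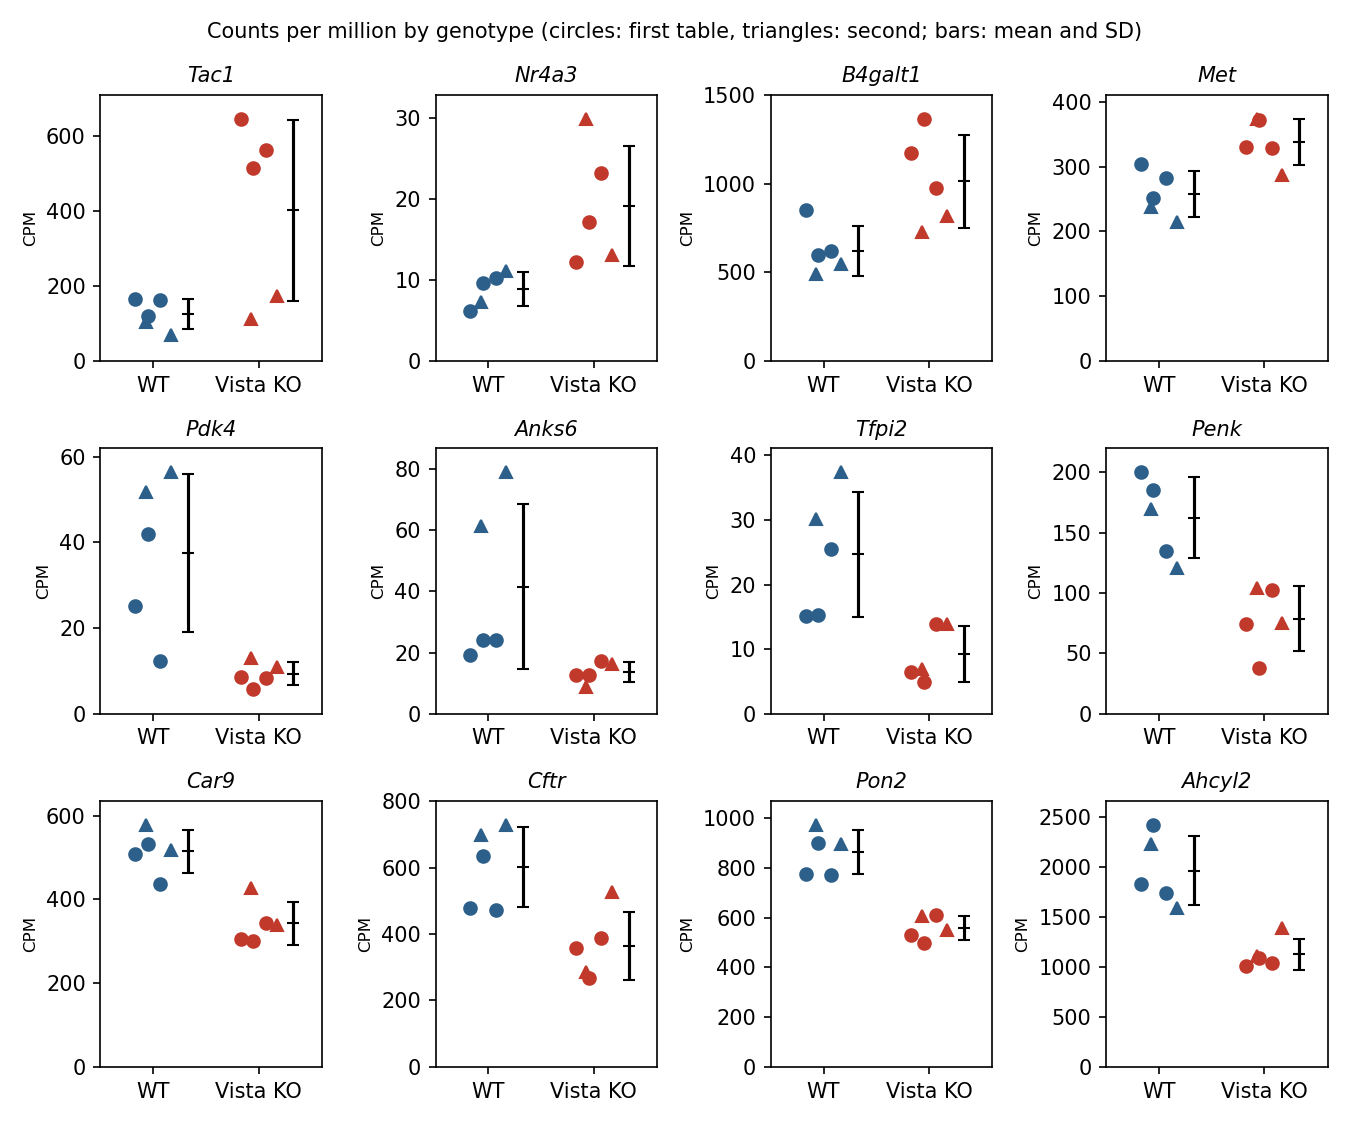
CPM of 12 genes inside the regions in the 5 WT and 5 knockout libraries, with circles for the first table, triangles for the second, and bars for the mean ± SD. For Tac1 the 3 first-table knockout libraries sit between 513 and 644 CPM, and the second-table ones at 112 and 173.

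Over the whole table, 548 of 9736 rows differed between genotypes by edgeR, 263 higher and 285 lower, of which the 38 above lie where names are used. On the first principal component of log2 CPM, which held 37.6% of the variance, the 2 WT libraries of the second table stood apart from the other 8. They lay at 44.4 and 48.3, and the other libraries between −25.4 and 5.88. The other 8 were not all alike. Knockout 4 lay highest on the second component, at 28.71, and its mean chi-square per row against knockouts 1 to 3 was 14.98 to 22.07. Without WT 4, WT 5 and the table covariate, an alternative added after the data were seen, 78 rows were called. Of these, 6 lay inside the regions, and 5 of those were among the 38. Leaving out 1 library gave 226 calls without WT 4, 237 without WT 2, 260 without knockout 2, 262 without WT 5, 308 without knockout 1, 314 without WT 1 and 990 without knockout 5. Inside the regions the values were 17 without WT 4, 20 without WT 2 or WT 5, 22 without knockout 2, 24 without knockout 1 and 59 without knockout 5.

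**Figure D3:**
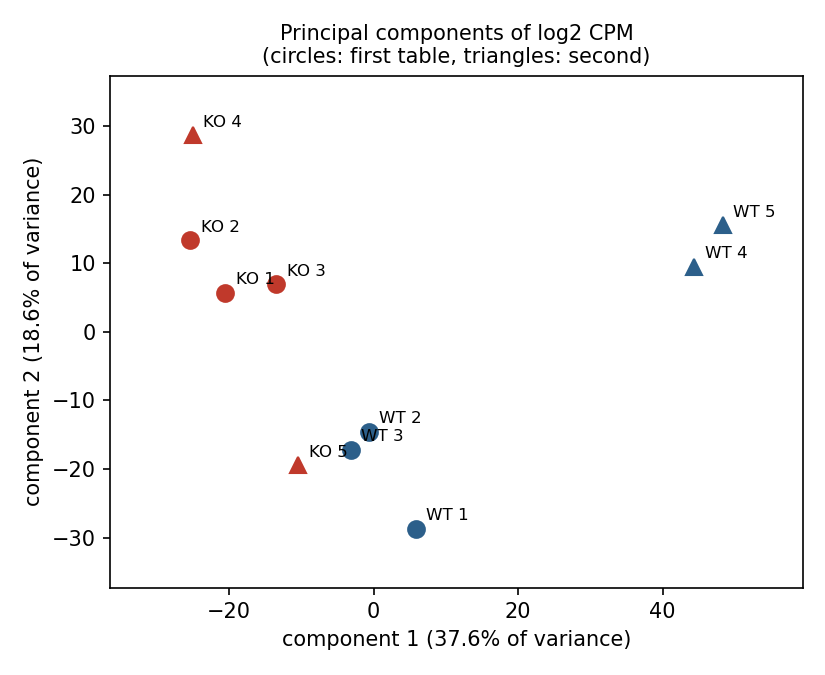
The 10 libraries on the first component (37.6% of variance) and second component (18.6% of variance) of log2 CPM, with circles for the first table and triangles for the second. WT 4 and WT 5 lie at 44.4 and 48.3 on the first component, and all others at 5.88 or below.

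The first table alone, the comparison of 3 against 3 that the design text describes, put Tac1 (log2 1.98, adjusted p 0.000145 in edgeR), Pdk4 (−1.76, 0.0294) and Ahcyl2 (−0.90, 0.00611) past the threshold with the signs of the pooled comparison. Inside the regions, 45 of 427 rows were called, 11 higher and 34 lower, and 22 of these were among the 38 pooled calls. Over all rows, 596 of 9829 were called, 305 higher and 291 lower. The count was 158 without WT 2, 183 without knockout 1, 250 without WT 3, 261 without knockout 2 and 348 without WT 1.

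In the second table, with 2 libraries of each genotype, Pdk4 (log2 −2.16, adjusted p 0.0256 in edgeR) and Anks6 (−2.47, 0.0473) were lower in the knockout, and Pax5, the B-cell transcription factor gene, was higher (3.73, 0.0315). Inside the regions 6 of 437 rows passed, 2 higher and 4 lower. Over all rows, 85 of 9932 passed, 53 higher and 32 lower. Leaving out any 1 library leaves 1 genotype with 1 library, so how far these calls rest on single libraries cannot be told. Of rows tested in both tables, 29 passed in both and 27 of these had the same sign, against 2.38 if the calls of each were independent. Of first-table calls, 81.7% had the same sign in the second. Across rows, which are not independent replicates, Pearson's r of the log2 fold changes was 0.273.

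Whether the genotype effect differed between the tables was tested as an interaction. Anks6 was −0.63 in the first table and −2.47 in the second, with an adjusted interaction p of 0.0202 in edgeR. Its level was 61.2 and 78.8 CPM in WT libraries 4 and 5, 19.2 to 24.2 in WT libraries 1 to 3 and 8.89 to 17.1 in the knockout libraries. Pax5 was −0.85 in the first and 3.73 in the second, with an adjusted p of 0.00377, and its pooled change of 0.63 did not pass. Pax5 stood at 10.7 and 5.15 CPM in WT libraries 4 and 5, which lie apart on the first component, and at 61.2, 134 and 148.4 CPM in WT libraries 1 to 3. Inside the regions 11 rows had an interaction, 9 with a higher and 2 with a lower effect in the second table. Over all rows 200 did, 171 higher and 29 lower.

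The fixed gene lists reached few genes whose names can be used. Of 784 symbols, 257 had a tested row, and 12 of those lay inside the regions, in 11 lists. Among them, Tac1 of the enteroendocrine list rose, and Pdk4 of the fatty acid oxidation list and Car9 of the hypoxia list fell. Of the 12, 8 did not pass in edgeR. The interferon response gene Ddx58 had a log2 fold change of 0.32, the goblet cell gene Spink4 −0.11 and the collagen gene Col1a2 −0.09. The smooth muscle gene Tpm2 had −0.41, Sdc2 −0.17, Cox6c −0.33, Ndufa4 −0.25 and Pax5 0.63. Col1a2, Spink4 and Pax5 changed sign when single libraries were left out. With no filter on low counts, Pax5 and Tpm2 passed in edgeR, with adjusted p values of 0.00115 and 0.00926, and Cox6c passed without knockout library 1, with 0.0323. Adjusted over the list alone, 1 member passed in the enteroendocrine list, 3 in the fatty acid oxidation list and 4 in the hypoxia list, counting rows outside the regions. Of 39 lists with enough members, camera put 0 past an adjusted p of 0.05, and 4 had an unadjusted p under it. The smallest adjusted p was 0.185, for bile acid and xenobiotic metabolism, and 0.787 with an estimated correlation. The test fry, which asks only whether a list's rows move one way, passed 7. Most members of these lists lie outside the regions, so list results there concern rows, not the named genes.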

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

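The test of the second table's processing, and the count of splits that keep its genotypes apart, were chosen only after the result was seen. In Ahcyl2, 1 knockout library, number 5, stood apart at 1391 CPM from the other 4, and in Slc35a1 WT library 1 stood apart at 575.2 CPM. Of 88 groups examined for such a library, these 2 stood out, and 4.4 would by chance at 1 in 20. The genotype effect differed between tables in 200 rows, among them Anks6 with an adjusted interaction p of 0.0202 and Pax5 with 0.00377 in edgeR.

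The WT libraries of the second table lay apart from all others on the first component, shifted by 45.6 from the WT libraries of the first table. A shift along this component shared by the whole table would move its knockout libraries too. Their mean moved by 2.05, or 4.503% of the WT shift, which argues against such a shift. That argument partly restates how the pattern was seen. The mean covers knockout 4 at −25.04 and knockout 5 at −10.41, which lay at 28.71 and −19.4 on the second component and were the farthest pair within a genotype. By mean chi-square per row, knockout 4 lay 14.98 to 22.07 from knockouts 1 to 3, and knockout 5 lay 9.12 to 15.09 from them. Knockouts 1 to 3 lay 6.1 to 9.98 from each other. A difference between the tables in directions other than the first component is therefore not excluded. Processing that reached only some libraries of the table is not excluded either. A difference between these mice or samples, or a wrong label, was not tested and stays open, since no row checks the genotype.

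Over 94 splits of the libraries, 2 gave as many interaction rows as the real 200, the real one included. The highest other, with 1002, set knockout 1 to 3 and WT 4 and 5 against the rest, which by construction turns the genotype effect into the interaction, so it points to the structure of the samples. The share over all 94 splits cannot decide whether chance explains the count. The count depends on the contrast within the second table, and 75 of the splits mixed the genotypes there. Of 19 splits that kept WT 4 and 5 apart from knockout 4 and 5, 2 gave as many and the others 20 to 174, so among these chance is not excluded. The 75 splits that mixed the pairs gave a median of 0 and at most 87.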

How the results depend on the processing

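The count inside the regions and every alternative of it, and the omission of both second-table WT libraries, were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate numbers shared between genotypes. With no filter on low counts, the pooled, first-table, second-table and inside counts were 1260, 1322, 2 and 85. With DESeq2, the pooled, second-table, interaction and inside counts were 828, 418, 341 and 61, and with voom the second table had 152. With a log2 fold change of at least 1, 201 pooled rows passed, 11 of them inside. Leaving out both second-table WT libraries and the covariate left 78 and 6, and turned Vsir to −0.47. The second table alone gave 6 inside. Leaving out 1 library gave 226 to 990 pooled calls, 158 to 456 in the first table and 17 to 59 inside. In the second table it leaves 1 genotype with 1 library, so no count is given. For Vsir the range was −0.022 to 0.98, the lowest without WT 5, and voom gave −0.74. For the lists, fry gave 7, the first table alone 1, and leaving out 1 library 0 to 1. Of single genes, Pax5 turned to −0.44 with voom and ran from −0.012 (without WT 5) to 1.08 as single libraries were left out, Spink4 from −0.44 to 0.053 (without knockout 4), and Col1a2 from −0.29 to 0.033 (without knockout 2), with 0.031 without WT 3. The cause of these differences was not tested. The omissions change the number and the identity of the libraries together, and the 990 without knockout 5 went the other way.

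The region rule moved the inside count from 16 to 61 over 24 rules, with more rows lower than higher in 24 of 24. All 24 rules use the same pooled calls and overlap on chromosome 4, so they are not separate checks of the direction. With tissue-restricted family members kept it was 22, and the chromosome 6 region, which holds Tac1, Pdk4 and Cftr, was lost. The regions left on chromosomes 4 and 15 then held 666 rows together. The chromosome 4 region alone held 788 under the rule in use, so it shrank too. Which of its named genes then fell outside was not examined. With a minimum of 1000 counts and runs of 10 it was 32, and the chromosome 15 region, with Adamts12, Ank, Cmbl and Rida, was lost. Of the 32 named genes called, 14 passed in all of 18 alternatives of the pooled fit, 18 lost the call in at least 1, and 0 changed sign. The alternatives counted here do not include leaving out both second-table WT libraries together with the table covariate, which kept 5 of the 38 calls inside the regions, or the fold minimum, which kept 11. At 1.5-fold, 43.3% of simulated changes were recovered in the pooled fit, so changes of that size can be missed; sequencing depth itself was not varied.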

Other observations

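The second position scan, and the test of shallow sequencing, were chosen only after the result was seen. The genotype differences were set against chance first. Of 100 splits of the 10 libraries, 1, the real one, gave as many as 548 rows, and the highest other gave 1. Chance can therefore be excluded for the whole table, in splits drawn without regard to the deposited table. Inside the regions 1 of 100 gave as many as 38, and the highest other gave 0. The inside calls are part of the whole-table calls under the same adjustment. The low inside counts of the other splits therefore followed from the first result and are no second test. The first table allows 10 splits, too few for a share under 0.05; the real one gave 596, the highest other 0, and 1 reached the real value. Rows flanking the targeted locus could differ through strain sequence carried along with it. Of the calls, 1.095% lay within 20 Mb of Vsir, against 1.53% of tested rows. A share that low was set beforehand as counting against flanking sequence, but the test is void, because the locus lies outside the regions and a row name there does not say which transcript was counted. The 38 calls inside the regions, where positions are used, lie on chromosomes 4, 6 and 15. Vsir is on chromosome 10, so these calls are not rows flanking it. For calls outside the regions, flanking sequence stays open.

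Genes used by every cell were nearly empty outside the regions, and shallow sequencing, which fills no silent gene, is argued against by 64 olfactory and vomeronasal receptor rows with 500 counts or more there. If names had come apart from transcripts only outside, total counts would separate protein-coding from pseudogene and lincRNA rows better inside, and the area under the curve was 0.878 inside and 0.751 outside, a difference of 0.1275 (95% interval 0.105 to 0.150), in line with that, though counts outside still followed gene class in part. A candidate cause, counting with an annotation of another mouse build than the alignment, was tested by scanning exonic counts against exons of universally used genes, and a first scan gave 0 of 20 chromosomes with a peak away from 0, the outcome set beforehand as counting against it, but was void, since 1970 of 2000 shuffles (98.5%) also peaked at 0. One revised scan, standardised by shuffles and designed after that outcome, gave 14 of 20 chromosomes with a peak 1 kb or more from 0 above every shuffle, such as 159.4 kb on chromosome 10, while its control, a peak at 0 inside the regions, exceeded every shuffle on chromosome 4 but not on 6 or 15. Outside the regions, the peak exceeded every shuffle on chromosome 6 but not on chromosomes 4 and 15. The scan cannot decide on a build mismatch, because its shuffles also broke up any clustering of counted rows along a chromosome. Such a mismatch remains a hypothesis found and tested on the same data.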
